A study of Zea mays with 9 samples.

How the data were processed

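RNA sequencing was carried out on maize seeds at germination. The 9 libraries fall into 3 groups of 3 biological replicates: CK, NaCl and NaCl+MT. The series title names exogenous melatonin (MT here), an indoleamine, and salt stress; the labels do not explain CK, which is the usual label of an untreated control, and give no dose or time of treatment. Total RNA was the starting material, with a Tiangen kit for RNA and an NEB kit for mRNA libraries.

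The deposited table holds 1 FPKM value (fragments per kilobase of gene, scaled to the mapped fragments of the library, computed by the authors) per gene and library for 39301 genes. The submitters' processing notes name HISAT2, featureCounts and DESeq2 and the genome build B73 RefGen_v3, without versions or the role of each. Read totals and gene lengths are not given, and an unnamed last column of the table is empty and was not used. Relative depth was estimated from the steps between the FPKM values of low genes, where 1 step is the value of 1 read. Of 6856 low genes examined, 2901 gave such a step, with a tolerance of 0.06 reads for a whole read. Multiples of the step held for 96.8% of the values of CK replicate 2, 98.5% of NaCl replicate 3 and 100% of the other libraries. The genes were chosen for whole multiples in the libraries with a clear step, so the 100% was fixed in advance. In CK replicate 2 and NaCl replicate 3 the step was at first open by a factor of 2, and it was settled from the values of these genes. With CK replicate 1 set to 1, depth ran from 0.537 in NaCl replicate 3 to 1.82 in CK replicate 2. The absolute depth stays unknown, so no counting intervals were computed.

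Gene IDs of the table were matched to a RefSeq gene table of the assembly Zm-B73-REFERENCE-NAM-5.0, which served for names only, since it belongs to another build and coordinates were not used. Of the IDs, 18908 matched, 18387 of them to exactly 1 RefSeq gene, and 521 matched several and were left unnamed. A gene name other than a locus number was available for 2015 (9.00%) of the tested genes. The reference gives no product names, so 32 gene lists fitting a germinating seed under salt were made by matching symbols to patterns. They hold 508 genes, 389 of them tested.

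Genes with an FPKM of at least 1 in at least 3 libraries were tested, 22379 in all. Values were taken as log2(FPKM + 1), so fold changes of genes near 0 are drawn towards 0. limma 3.58.1 in R 4.3.3 fitted 1 model with 3 group means and a mean-variance trend, and its moderated test was made for NaCl against CK, NaCl+MT against NaCl and NaCl+MT against CK. P-values were adjusted by Benjamini-Hochberg over the tested genes of each comparison, with a threshold of 0.05. All p-values given for genes are 2-sided and adjusted, and all SE values are those of the moderated fit. Means and SD are of FPKM over 3 replicates. Gene lists with at least 5 tested members, 25 of the 32, were tested with camera at a preset correlation of 0.01 and adjusted over the lists. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance one way, were run beside it. Counts of list members past the threshold are given over all tested genes, and for the lists called also adjusted over the list alone.

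The comparisons NaCl against CK and NaCl+MT against NaCl share the NaCl libraries, so their fold changes are negatively correlated by construction. Their overlap was set beside the overlap of independent lists and beside 20 simulations of unchanged groups that share libraries in the same way. On simulated data with 200 of 22379 genes changed, the fit found 56 to 61% of genes changed by 1 on the log2 scale and 91 to 94% of those changed by 2. False calls made up 3.77%, 6.92% and 3.23% of the calls of the 3 comparisons. The simulated noise was normal with the same spread in every group, and far fewer genes were changed than were called in the data. In the data the NaCl replicates differed most, so these rates need not hold for the real comparisons.

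Groups, tests, gene lists, alternatives and the rule for named genes were set before the data were examined. The rule took, for NaCl against CK and for NaCl+MT against NaCl, up to 2 members per list with the largest change past the threshold and without overlap of the groups. Where a list had none past the threshold, it took the member with the highest mean. It added the 5 largest rises and 5 largest falls among named genes in each of these comparisons, the 6 named genes with the largest changes in opposite directions, up to 4 with the same direction in both, and 3 rises and 3 falls for NaCl+MT against CK. Among the genes so chosen, those described below were mostly ones whose call held without any single library; the rest of a list is given as counts.

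Alternatives covered pseudocounts of 0.1 and 0.5, no filter, a minimum of 5 FPKM, median-ratio scaling, quantile normalisation, a constant sum per library, a fit without trend, array weights, the replicate number as a block, fits on the 6 libraries compared, a fold threshold of 1 on the log2 scale, and leaving out each library in turn. After the data were seen, the counts were also computed without both NaCl replicates 1 and 3, and the lists were tested without symbols judged by name to belong to another family, a judgement that left in TPS17, GLB1 and ss2, whose families also differ from those of their lists. Figures were drawn with matplotlib 3.10.9, and tables were prepared with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15. The table's empty column and genes under the filter were left out, the latter because their values rest on few reads.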

Results

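Gene expression was measured by RNA sequencing in germinating maize seeds of 3 groups with 3 biological replicates each: CK, NaCl and NaCl+MT, by its label salt and melatonin. The labels do not say whether melatonin came before or with salt. Of 39301 genes in the deposited FPKM table, 22379 were expressed highly enough to be tested. Relative to CK replicate 1, the depth was 1.82 and 1.28 in CK replicates 2 and 3, 1.16, 1.25 and 0.537 in NaCl replicates 1 to 3, and 0.970, 1.01 and 0.891 in NaCl+MT replicates 1 to 3. The shallower NaCl replicate 3 listed 12558 genes at 0, against 9986 to 10802 in the other 8 libraries. In NaCl replicate 1 the 20 highest genes held 11.5% of the FPKM sum, the largest share of the 9 libraries, where the lowest was 6.71%.

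The NaCl libraries stood apart from the other 6. The first principal component held 57.8% of the variance and the second 12.8%. On the first component CK libraries lay at -45.3, -35.6 and -47.1, NaCl+MT libraries at -15.8, -25.6 and -22.3, and NaCl libraries at 88.4, 46.2 and 56.9. Correlations across genes, which are not independent replicates, were 0.973 to 0.984 within CK, 0.938 to 0.974 within NaCl and 0.974 to 0.992 within NaCl+MT. Between groups they were 0.840 to 0.927 for CK and NaCl, 0.877 to 0.942 for NaCl and NaCl+MT, and 0.949 to 0.978 for CK and NaCl+MT.

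**Figure D1:**
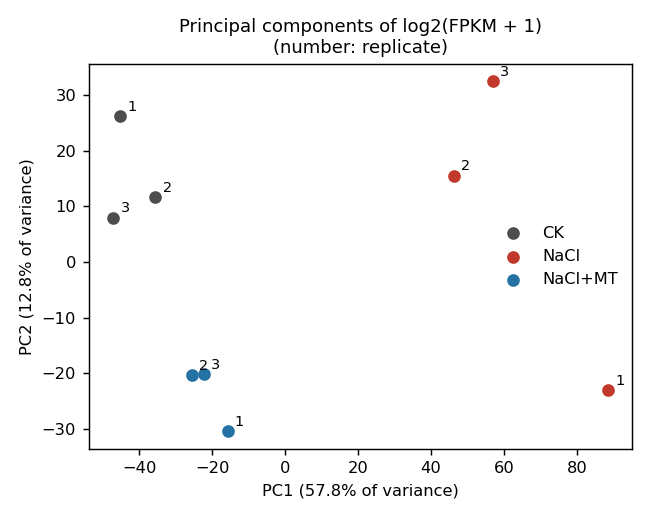
First and second principal components of log2(FPKM + 1) over the 22379 tested genes, 1 point per library and 1 colour per group. The 3 NaCl libraries lie at 46.2 to 88.4 on the first component, the other 6 at -47.1 to -15.8.

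The comparison of NaCl with CK shows how seeds germinating with salt differed from control seeds. The flavonoid gene c2 (GRMZM2G422750), which encodes chalcone synthase, had an FPKM of 0.411 ± 0.216 (SD, n = 3) in CK and 20.1 ± 3.90 in NaCl, a log2 fold change of 3.90 (SE 0.29, limma adjusted p = 1.29e-05). The pathogenesis-related gene pr5 (GRMZM2G402631) rose from 124 ± 14.9 to 1571 ± 1022 (log2 fold change 3.47, SE 0.42, adjusted p = 0.000283). PDC (GRMZM2G038821), pyruvate decarboxylase of ethanolic fermentation, rose from 2.19 ± 0.574 to 23.5 ± 5.22 (2.94, SE 0.20, adjusted p = 7.18e-06). The cell cycle gene cyc1 (GRMZM2G034647), a cyclin, fell from 9.64 ± 3.23 to 0.115 ± 0.0746 (-3.21, SE 0.24, adjusted p = 1.33e-05), and the tonoplast aquaporin gene tip2b (GRMZM2G056908) fell from 25.7 ± 14.4 to 1.37 ± 0.902 (-3.44, SE 0.39, adjusted p = 0.000189).

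Further large rises were those of ME1 (GRMZM2G085019), an NADP-malic enzyme gene, from 2.30 ± 0.118 to 66.6 ± 53.6 FPKM (log2 fold change 3.86, SE 0.61, adjusted p = 0.00129), ARGOS8 (GRMZM2G354338), a negative regulator of ethylene responses, from 0.666 ± 0.287 to 16.5 ± 6.41 (3.35, SE 0.23, adjusted p = 8.25e-06), and the transcription factor gene ERF1 (GRMZM2G053503), from 23.8 ± 4.17 to 239 ± 103 (3.20, SE 0.28, adjusted p = 3.51e-05). Without NaCl replicate 1 or 2 the fold change of ME1 was 4.79 or 3.19. Among the falls, TPS17 (GRMZM2G010356), a terpene synthase gene, went from 19.4 ± 5.34 to 0.0647 ± 0.0993 (-4.24, SE 0.21, adjusted p = 1.62e-06) and hsbp1 (GRMZM2G085924) from 64.6 ± 28.5 to 2.11 ± 2.79 (-4.68, SE 0.65, adjusted p = 0.000623; -5.39 without NaCl replicate 1, -4.09 without NaCl replicate 3). The gene bx1 (GRMZM2G085381), the first step of benzoxazinoid synthesis, fell from 4489 ± 1577 to 178 ± 170 (-6.63, SE 1.61, adjusted p = 0.0132). The size of this fall rests on NaCl replicate 1, without which the fold change was -4.05, against -7.72 without NaCl replicate 2 and -8.12 without NaCl replicate 3.

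In all, 5808 genes (26.0% of those tested) changed with NaCl, 3042 of them higher and 2766 lower. Of these, 1186 rose and 1311 fell by at least 1 on the log2 scale. The 3 NaCl and 3 CK values did not overlap in 40.9% of the tested genes, where chance gives 10%. Higher genes made up 52.4% of the changed genes, and 44.5% after median-ratio scaling. Without both NaCl replicates 1 and 3, which stand apart by position and depth, 2597 genes changed.

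**Figure D2:**
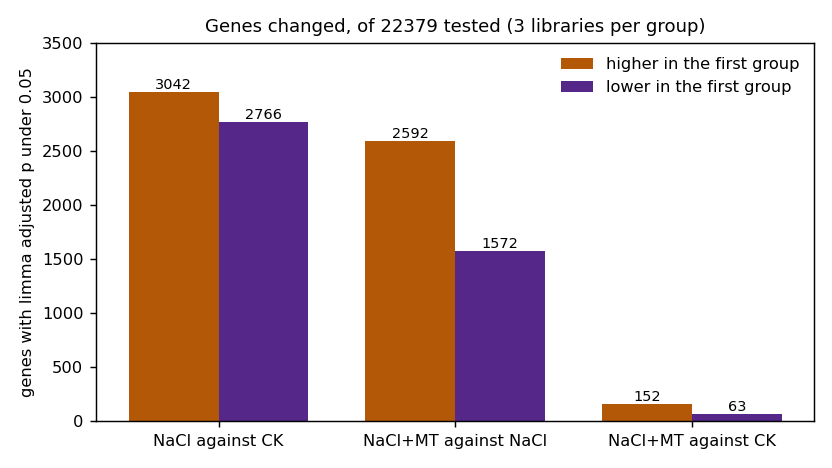
Number of genes past an adjusted p of 0.05 in each of the 3 comparisons, with 1 bar for genes higher and 1 for genes lower in the group named first. NaCl against CK gave 5808 genes, NaCl+MT against NaCl 4164 and NaCl+MT against CK 215.

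Of the 10 lists called in this comparison, 5 were lower with NaCl. In the cell cycle list 7 of 13 members fell and 1 rose (8 and 1 adjusted over the list alone; median -0.59, camera adjusted p = 0.00109, adjusted p = 0.388 with an estimated correlation), cyc3 (GRMZM2G073671) among them, from 8.70 ± 3.24 to 0.132 ± 0.168 FPKM. Of 9 genes of the histone list 6 fell (9 adjusted over the list alone; median -1.28, camera adjusted p = 0.00212, adjusted p = 0.402 with an estimated correlation). Without the linker histone genes his1 and his1a of this list, 5 of 7 fell (camera adjusted p = 0.00416). Of 20 aquaporin genes 8 fell and 1 rose (9 and 1 adjusted over the list alone; median -0.66, camera adjusted p = 0.00212, adjusted p = 0.402 with an estimated correlation), with nip2b (GRMZM2G137108) at 2.96 ± 1.21 in CK and 0.127 ± 0.156 in NaCl. Of 9 auxin genes 4 fell (4 adjusted over the list alone; median -0.55, camera adjusted p = 0.00416, adjusted p = 0.338 with an estimated correlation), among them the efflux carrier gene PIN1a (GRMZM2G098643), from 19.6 ± 1.32 to 6.14 ± 0.848. In the ribosomal protein list 1 of 27 members fell, rpl19 (GRMZM2G171444), from 32.9 ± 3.63 to 19.4 ± 3.19 (1 adjusted over the list alone; median -0.36, camera adjusted p = 0.00755, adjusted p = 0.620 with an estimated correlation). Without NaCl replicate 1 this last list was not called (camera adjusted p = 0.0646; over all camera alternatives 0.000583 to 0.620).

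The other 5 lists called were higher with NaCl. Of 10 heat shock genes 4 rose (5 adjusted over the list alone; median 0.68, camera adjusted p = 0.00416, adjusted p = 0.301 with an estimated correlation), with hsp18c (GRMZM2G034157) at 2.89 ± 0.438 FPKM in CK and 9.66 ± 0.392 in NaCl. Of 13 protease and amylase inhibitor genes 5 rose (7 rose and 2 fell adjusted over the list alone; median 0.80, camera adjusted p = 0.0227, adjusted p = 0.402 with an estimated correlation), among them wip1 (GRMZM2G156632), a wound-induced Bowman-Birk type inhibitor, from 89.1 ± 24.2 to 785 ± 647 (log2 fold change 2.86, and 2.23 without NaCl replicate 1). Of 31 glutathione S-transferase genes 12 rose and 3 fell (13 and 3 adjusted over the list alone; median 0.42, camera adjusted p = 0.0227, adjusted p = 0.388 with an estimated correlation), with gst7 (GRMZM2G028556) at 5.78 ± 0.618 in CK and 45.6 ± 14.7 in NaCl. The phenylpropanoid list, in which 6 of 12 members rose and 1 fell (6 and 1 adjusted over the list alone; median 1.02, camera adjusted p = 0.0227, adjusted p = 0.402 with an estimated correlation), includes the chitinase genes chiA and chiI, which belong to another pathway, and without such members its 7 others gave a camera adjusted p of 0.0834. Of 34 abscisic acid signalling genes 11 rose and 2 fell (11 and 2 adjusted over the list alone; median 0.24, camera adjusted p = 0.0395, adjusted p = 0.388 with an estimated correlation). The phosphatase gene PP2C16 (GRMZM2G082487) of that list rose from 5.17 ± 0.761 to 17.7 ± 2.38. Without CK replicate 1 the camera adjusted p was 0.0840 for the glutathione S-transferase, phenylpropanoid and abscisic acid lists; the last was also not called without NaCl replicate 1 (0.0778), without NaCl+MT replicate 1 (0.0548), or without symbols of other families (0.0727). Over all alternatives run with camera the lowest adjusted p of these 3 lists was 0.00345, 0.0129 and 0.0216, and the highest that with an estimated correlation.

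The other 15 lists tested were not called in this comparison. In the jasmonate list 6 of 28 rose and 8 fell (camera adjusted p = 0.238), with the lipoxygenase gene lox10 (GRMZM2G015419) at 10.4 ± 4.63 FPKM in CK and 0.210 ± 0.0260 in NaCl. This list takes all lox, aos, aoc, opr and zim symbols, so not every member need serve jasmonate synthesis. Of 24 ERF genes 7 rose and 5 fell (0.309), of 15 WRKY genes 5 rose and 1 fell (0.286), and of 17 NAC genes 3 rose and 1 fell (0.411). Of 18 sodium and potassium transport genes 5 rose and 1 fell (0.373). In the compatible solute list 3 of 12 rose and 4 fell (0.572; median 0.22, mean -0.51), where the fallen TPS17 and tps26 are terpene synthase genes, whose symbols match those of trehalose phosphate synthases. Of 13 cell wall genes 3 rose and 3 fell (0.689; median 0.09, mean -0.36), and of 5 fermentation genes 2 rose and 1 fell (0.479; median -0.04, or 0.06 after quantile normalisation, mean 0.37). Of the storage protein and oleosin genes 2 of 8 rose (0.193). Both calls were lost without CK replicate 3 (limma adjusted p = 0.103 and 0.0513), and 1 of them also without CK replicate 2 (0.0675) or NaCl replicate 3 (0.0886). GLB1 and zpu1 of this list are a haemoglobin and a starch debranching enzyme gene. The gibberellin list had 2 of 10 higher and 2 lower (0.664, direction up). Of its symbols 5 belong to other families, and without them 1 of 5 was higher and 2 lower (0.670, direction down). Starch synthesis had 1 of 15 higher and 2 lower (0.303), and the antioxidant list 2 of 10 lower (0.209). Falls were seen in 1 of 5 late embryogenesis abundant protein genes (0.468), 1 of 6 peroxidase genes (0.0981) and 1 of 6 protease genes (0.373). The late embryogenesis abundant protein list had a median of 0.46 and a camera direction of up. Adjusted over that list alone, 2 of its genes rose and 1 fell. Lists under 5 tested members were not tested: 2 of 4 pathogenesis-related genes rose, and 1 of 4 starch breakdown genes fell, which was Amy2 (GRMZM2G058310; 40.3 ± 7.87 in CK, 17.1 ± 4.74 in NaCl). In the photosynthesis list only rbcS (GRMZM2G098520), the small subunit of Rubisco, fits by its name, at 0.862 ± 0.515 in CK and 0.291 ± 0.224 in NaCl (adjusted p = 0.121). The 1 of its 4 genes that fell, PSA2, is a photosystem assembly factor. Its call was lost without CK replicate 1 (adjusted p = 0.0807), CK replicate 2 (0.0507) or NaCl replicate 3 (0.0522), with a range of 0.0152 to 0.143 over all alternatives. In the abscisic acid metabolism list of 4 genes 1 rose and 1 fell. The fall, of AO1 (GRMZM2G141535), was lost without CK replicate 1 (limma adjusted p = 0.0867), CK replicate 3 (0.0547) or NaCl replicate 3 (0.0673). None of 3 lipid breakdown genes passed the limma threshold, with isocitrate lyase (ICL, GRMZM2G056369) at 2107 ± 480 in CK and 2083 ± 364 in NaCl. The melatonin pathway list had 0 members with a matching symbol.

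**Figure D3:**
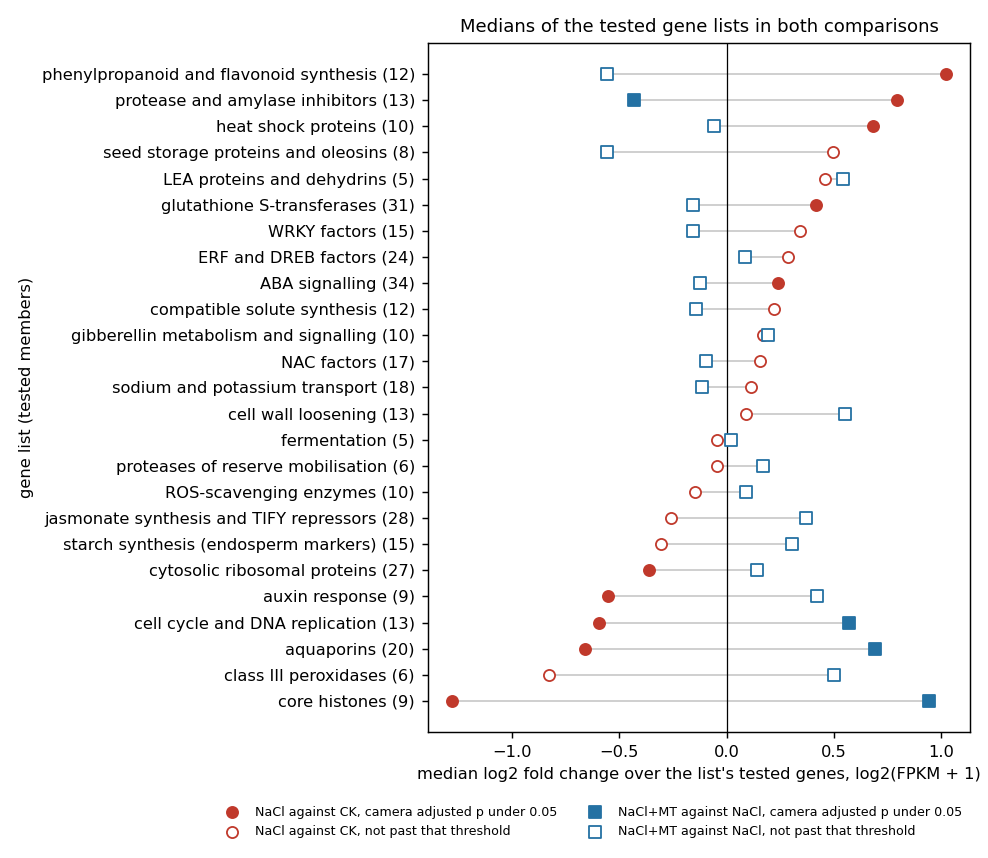
Median log2 fold change of each of the 25 tested gene lists in NaCl against CK (circles) and NaCl+MT against NaCl (squares), filled where camera gave an adjusted p under 0.05, with the number of tested members in parentheses. The cell cycle list has a median of -0.59 in NaCl against CK and 0.57 in NaCl+MT against NaCl.

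The comparison of NaCl+MT with NaCl shows what differed between salt-treated seeds with and without melatonin. The cyclin gene cyc1 rose from 0.115 ± 0.0746 to 5.08 ± 1.52 FPKM (SD, n = 3; log2 fold change 2.42, SE 0.24, limma adjusted p = 0.000141), and tip2b rose from 1.37 ± 0.902 to 25.1 ± 8.64 (3.47, SE 0.39, adjusted p = 0.000291). The lipoxygenase gene lox10 rose from 0.210 ± 0.0260 to 11.6 ± 1.89 (3.36, SE 0.29, adjusted p = 5.74e-05). PDC fell from 23.5 ± 5.22 to 2.70 ± 0.2997 (-2.71, SE 0.20, adjusted p = 2.71e-05), and wip1 fell from 785 ± 647 to 47.2 ± 22.2 (-3.86, SE 0.53, adjusted p = 0.000867; -3.22 without NaCl replicate 1).

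Other large rises with NaCl+MT were those of kin1 (GRMZM2G158394), from 0.686 ± 0.140 to 28.0 ± 4.42 FPKM (log2 fold change 4.10, SE 0.25, adjusted p = 1.09e-05), and glu2 (GRMZM2G008247), from 0.191 ± 0.212 to 11.6 ± 0.725 (3.41, SE 0.18, adjusted p = 6.70e-06). Large falls were those of ARGOS8, from 16.5 ± 6.41 to 1.20 ± 0.0326 (-2.94, SE 0.23, adjusted p = 3.57e-05), and CNR2 (GRMZM2G151230), from 199.8 ± 65.9 to 23.9 ± 5.51 (-2.98, SE 0.26, adjusted p = 6.54e-05). Chalcone synthase c2 fell from 20.1 ± 3.90 to 3.29 ± 2.06 (-2.39, SE 0.29, adjusted p = 0.000432), and ME1 from 66.6 ± 53.6 to 2.51 ± 0.347 (-3.77, SE 0.61, adjusted p = 0.00214; -4.71 without NaCl replicate 1, -3.11 without NaCl replicate 2). The benzoxazinoid gene bx1 had 178 ± 170 in NaCl and 2427 ± 239 in NaCl+MT (5.81, SE 1.61, adjusted p = 0.0306), a call that was lost without NaCl+MT replicate 1 (adjusted p = 0.0808), 2 (0.0839) or 3 (0.0796), with 0.000205 as the lowest value over all alternatives. Its fold change was 3.23 without NaCl replicate 1, 6.90 without NaCl replicate 2 and 7.30 without NaCl replicate 3.

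In all, 4164 genes (18.6%) differed between NaCl+MT and NaCl, 2592 higher and 1572 lower. Of these, 1196 rose and 604 fell by at least 1 on the log2 scale. Values did not overlap in 36.6% of the tested genes, where chance gives 10%. The count was 2325 without NaCl+MT replicate 2, 2401 without NaCl+MT replicate 3 and 1754 without both NaCl replicates 1 and 3. Higher genes made up 62.2% of the changed genes, and 51.5% after quantile normalisation.

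Of the 25 lists tested, 4 were called in this comparison, each against its direction in NaCl against CK. Both comparisons share the NaCl libraries, which favours opposite directions, and how far this holds for lists was not tested. Of 20 aquaporin genes 6 rose and 1 fell (11 and 1 adjusted over the list alone; median 0.69, camera adjusted p = 0.00274, adjusted p = 0.391 with an estimated correlation), with tip2 (GRMZM2G168439) at 3.90 ± 2.34 FPKM in NaCl and 15.4 ± 2.25 in NaCl+MT. Of 13 cell cycle genes 6 rose and 1 fell (8 and 1 adjusted over the list alone; median 0.57, camera adjusted p = 0.00589, adjusted p = 0.391 with an estimated correlation), and of 9 genes of the histone list 4 rose (9 adjusted over the list alone; median 0.94, camera adjusted p = 0.00589, adjusted p = 0.391 with an estimated correlation). Without the linker histone genes his1 and his1a 2 of 7 rose (camera adjusted p = 0.0275). The rise of the histone gene his2b2 (GRMZM2G119071) was lost without any CK or NaCl+MT replicate taken singly (limma adjusted p = 0.058 to 0.132). Of 13 protease and amylase inhibitor genes 4 fell (4 adjusted over the list alone; median -0.43, camera adjusted p = 0.00665, adjusted p = 0.391 with an estimated correlation), with the cystatin gene cc6 (GRMZM2G401328) at 838 ± 87.9 in NaCl and 204 ± 43.2 in NaCl+MT. Without NaCl replicate 3, 7 lists were called.

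The remaining lists were not called. Of 34 abscisic acid signalling genes 8 fell and 3 rose (camera adjusted p = 0.0952), with PP2C16 at 8.06 ± 0.700 FPKM in NaCl+MT against 17.7 ± 2.38 in NaCl. Of 28 genes of the jasmonate list 8 rose and 3 fell (0.0952), among the former lox6 (GRMZM2G040095), from 4.49 ± 0.746 to 25.5 ± 0.894. Of 12 phenylpropanoid genes 5 fell and 2 rose (0.0883), of 31 glutathione S-transferase genes 4 fell and 3 rose (0.187), and of 10 heat shock genes 4 fell and 1 rose (0.187). Of 9 auxin genes 3 rose and 1 fell (0.125), and of 13 cell wall genes 5 rose and 1 fell (0.207), with the xyloglucan-modifying gene xth1 (GRMZM2G119783) at 3.56 ± 2.29 in NaCl and 27.2 ± 7.70 in NaCl+MT. Of the compatible solute genes 3 of 12 rose and 2 fell (0.920; median -0.14, mean 0.35). The camera direction of this list was up, but down without tps26 (0.761), and TPS17 stayed in the list in both tests. Of 5 fermentation genes 1 rose and 2 fell (0.207; median 0.02, mean -0.43), the rise being the alcohol dehydrogenase gene adh2 (GRMZM2G098346), from 23.1 ± 15.7 to 81.6 ± 15.7. Counts of rises and falls were 2 and 4 of 18 in sodium and potassium transport (0.260), 2 and 0 of 27 in ribosomal proteins (0.384), and 2 and 0 of 15 in starch synthesis (0.192). They were 5 and 3 of 24 in ERF (0.920), 1 and 2 of 15 in WRKY (0.209), and 1 and 4 of 17 in NAC genes (0.242). Of 5 late embryogenesis abundant protein genes 2 rose (0.207), dhn2 (GRMZM2G373522), a dehydrin gene, at 28.0 ± 11.0 in NaCl and 74.5 ± 5.53 in NaCl+MT. The call of the other, mlg3, was lost without any CK replicate, NaCl replicate 2, or NaCl+MT replicate 2 or 3 taken singly (limma adjusted p = 0.0631 to 0.161). A single member fell in the storage (0.168) and gibberellin (0.920) lists, a single member rose in the peroxidase (0.187) and antioxidant (0.467) lists, and no protease gene passed the limma threshold (0.757). The fall in the storage list, of ole1, was lost without CK replicate 2, NaCl replicate 2 or 3, or NaCl+MT replicate 2 or 3 (limma adjusted p = 0.0506 to 0.129). That in the gibberellin list, of KSL4, was lost without NaCl+MT replicate 2 (0.053) or 3 (0.0508). Adjusted over the list alone, 4 gibberellin genes rose and 3 fell. Of the lists too small to test, 3 of 4 genes of the photosynthesis list rose, of which only rbcS fits by its name (0.291 ± 0.224 in NaCl, 1.58 ± 0.0427 in NaCl+MT, adjusted p = 0.0105), 2 of 4 pathogenesis-related genes fell, and 1 gene of abscisic acid metabolism rose, while no gene of starch or lipid breakdown passed the limma threshold. The rise in abscisic acid metabolism, of AO1, was lost without NaCl replicate 3 (limma adjusted p = 0.0676), or NaCl+MT replicate 1 (0.0807) or 2 (0.0841).

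Many of the genes changed by NaCl were changed back with NaCl+MT. A fall with NaCl and a rise with NaCl+MT was seen for cyc1, tip2b, lox10, glu2 and kin1, and the reverse for PDC, ARGOS8, gst7 and c2. By group means alone the way back was not always complete: the NaCl+MT mean of cyc1 stayed below its CK mean, and that of c2 above its CK mean. In NaCl+MT against CK, however, 0 of 13 cell cycle genes passed the limma threshold, so cyc1 was not called different from CK. In all, 3073 genes (52.9% of those changed by NaCl) were past the limma threshold in both comparisons with opposite directions. Of these, 1247 rose with NaCl and fell with NaCl+MT, and 1826 fell and then rose. Independent lists of these sizes would share 214 genes of the former kind and 320.4 of the latter. By contrast, 5 genes rose in both comparisons and 0 fell in both, where independent lists would give 352 and 194. The 5 are the chaperone genes HSP90-1 (GRMZM2G024668), at 7.65 ± 0.784, 25.5 ± 2.24 and 34.6 ± 2.44 FPKM in CK, NaCl and NaCl+MT, and hsp101 (GRMZM2G360681), at 6.04 ± 0.397, 8.41 ± 0.874 and 13.8 ± 0.561, and GRMZM2G131715, GRMZM2G445616 and GRMZM2G702923, which carry no gene name. With 1 library left out, GRMZM2G131715 kept both calls in every fit. GRMZM2G702923 lost its call in NaCl against CK without any CK replicate or NaCl replicate 1 or 3 taken singly (adjusted p = 0.0515 to 0.0903). GRMZM2G445616 lost its call in NaCl against CK without CK replicate 2 (0.0741) or NaCl replicate 3 (0.0544). It lost that in NaCl+MT against NaCl without NaCl replicate 1 (0.0588) or NaCl+MT replicate 1 (0.0868) or 3 (0.0903). HSP90-1 lost its call in NaCl+MT against NaCl without CK replicate 2 or 3, NaCl replicate 2 or 3 or any NaCl+MT replicate (adjusted p = 0.0560 to 0.157), and hsp101 its call in NaCl against CK without any library other than NaCl replicate 3 and NaCl+MT replicate 1 (adjusted p = 0.0610 to 0.115).

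Because both comparisons use the NaCl libraries, their fold changes correlate negatively even for unchanged genes. Across genes the correlation was -0.87, against -0.50 in simulated unchanged groups, and the covariance was -0.384 against -0.0286. The simulations gave every group the same spread, while the NaCl replicates differed most. The SD of log2 differences between replicates was 0.401 to 0.614 in NaCl, 0.306 to 0.399 in CK and 0.206 to 0.377 in NaCl+MT. The simulations thus understate what the shared NaCl libraries alone would give. In 20 simulations of unchanged groups no gene passed the limma threshold in both comparisons with opposite directions. With no changed genes hardly any call is made, so this outcome does not tell how much of the overlap comes from the shared libraries. The 3 NaCl libraries are too few to give each comparison at least 2 of its own, so a part of the overlap may rest on the shared libraries. The count was 1858 of 4892 genes changed by NaCl without NaCl+MT replicate 2, 1934 of 4809 (40.2%) without NaCl+MT replicate 3 and 2509 of 5719 (43.9%) without NaCl+MT replicate 1. It was 1319 without both NaCl replicates 1 and 3.

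Of the 5808 genes changed by NaCl, 4391 (75.6%) had an NaCl+MT mean between those of CK and NaCl, 1182 (20.4%) had one past CK and 235 (4.05%) one beyond NaCl. The NaCl+MT mean was closer to CK than to NaCl for 4325 genes (74.5%). The median ratio of the change in NaCl+MT to that in NaCl, both against CK, was 0.275. It was 0.389 for genes higher with NaCl and 0.168 for genes lower with NaCl. All these genes were chosen for a large distance of NaCl from CK, which inflates that distance. The choice alone thus favours NaCl+MT means between CK and NaCl, nearer to CK, and a low ratio. A different measure took genes and directions from 2 CK and 2 NaCl libraries and the changes from the CK and NaCl libraries left out. There the ratio of the mean change in NaCl+MT to that in NaCl ran from 0.183 to 0.325 over the choices of left-out libraries. Among the genes changed in NaCl+MT against CK, 54.9% had an NaCl+MT mean beyond that of NaCl.

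**Figure D4:**
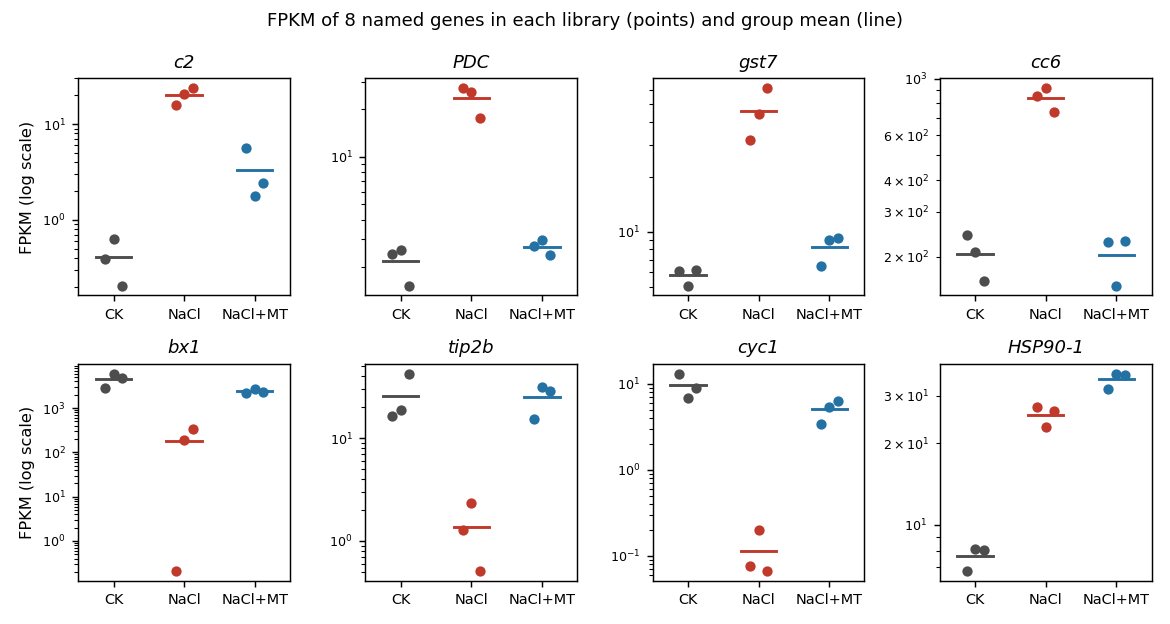
FPKM on a log axis in each of the 9 libraries for 8 named genes, 1 point per library, with the group mean of 3 replicates as a line. The cyclin gene cyc1 has a mean of 9.64 in CK, 0.115 in NaCl and 5.08 in NaCl+MT.

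The comparison of NaCl+MT with CK shows what differed from the control in seeds that received both salt and melatonin. The chaperone gene HSP90-1 rose from 7.65 ± 0.784 to 34.6 ± 2.44 FPKM (SD, n = 3; log2 fold change 2.04, SE 0.13, limma adjusted p = 0.000302). LOB15 (GRMZM2G060544) rose from 4.22 ± 0.145 to 14.2 ± 2.60 (1.53, SE 0.19, adjusted p = 0.00700), a call that was lost without NaCl+MT replicate 3 (adjusted p = 0.0569; lowest over all alternatives 6.49e-05). ERF1 was at 23.8 ± 4.17 in CK and 96.9 ± 21.8 in NaCl+MT (1.97, SE 0.28, adjusted p = 0.0163), with a call that was lost without CK replicate 1 (0.0752), CK replicate 3 (0.0587), or NaCl+MT replicate 1 (0.0808), 2 (0.0542) or 3 (0.0647); its lowest value was 0.000190. The auxin efflux carrier gene PIN9 (GRMZM5G859099) was at 7.90 ± 3.33 in CK and 0.475 ± 0.246 in NaCl+MT (-2.52, SE 0.36, adjusted p = 0.0163), with a call that was lost without CK replicate 1 (0.0756) or 2 (0.0533), or NaCl+MT replicate 1 (0.0793), 2 (0.0712) or 3 (0.0617), and a lowest value of 0.000169. The other named falls, CYPPDKZM2 and al1, were lost without any 1 of the CK and NaCl+MT libraries (adjusted p = 0.0515 to 0.113).

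In this comparison 215 genes changed, 152 higher and 63 lower, 98 and 48 of them by at least 1 on the log2 scale, and values did not overlap in 31.1% of the tested genes, where chance gives 10%. Of the 215, 163 were also changed by NaCl against CK, 160 in the same direction and 3 in the opposite one: ocl4 (GRMZM2G123140), GRMZM2G112799 and AC205574.3_FG006. The other 52, of which 40 were higher and 12 lower, were not past the threshold with NaCl. NaCl against CK and NaCl+MT against CK share the CK libraries, which favours equal directions. How much of the agreement comes from this was not computed. Of 5 late embryogenesis abundant protein genes 1 rose (2 adjusted over the list alone; median 0.61, camera adjusted p = 0.0205, adjusted p = 0.359 with an estimated correlation), and of 9 auxin genes 1 fell, PIN9 (4 adjusted over the list alone; median -0.15, camera adjusted p = 0.0205, adjusted p = 0.359 with an estimated correlation). The cell cycle list (0 of 13 past the limma threshold over all genes, 1 higher and 3 lower adjusted over the list alone; median -0.12, camera adjusted p = 0.0205, adjusted p = 0.628 with an estimated correlation) and the ribosomal protein list (0 of 27, 0 adjusted over the list alone; median -0.15, camera adjusted p = 0.0205, adjusted p = 0.630 with an estimated correlation) were also called. Of the other 21 lists none was called by camera, and 1 gene rose in each of the ERF (camera adjusted p = 0.0545), heat shock (0.0577), glutathione S-transferase (0.0703) and phenylpropanoid (0.0974) lists and 1 fell in the compatible solute list (0.236). In the remaining 16 tested lists and the 6 small ones no member passed the limma threshold. Without CK replicate 1 the camera adjusted p of these 4 lists was 0.06002, 0.0781, 0.0880 and 0.0880, so that 0 lists were called (10 at an unadjusted p under 0.05), against 8 without CK replicate 3 and 7 without NaCl+MT replicate 2. The gene count moved from 215 to 34, 51 and 47 without CK replicates 1, 2 and 3, to 33, 16 and 6 without NaCl+MT replicates 1, 2 and 3, to 875 without NaCl replicate 1, to 1068 without both NaCl replicates 1 and 3 and to 1082 in a fit of the 6 libraries compared, and higher genes made up 70.7% of it, or 45.5% after quantile normalisation.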

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

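Leaving out both NaCl replicates 1 and 3 and testing lists without most symbols of other families were chosen after the data were seen; the other alternatives were planned. No called list or named gene turned its direction past the threshold, but the share of higher genes among those changed did turn: 52.4% became 44.5% after median-ratio scaling in NaCl against CK, and 70.7% became 45.5% after quantile normalisation in NaCl+MT against CK. Medians of some lists that were not called also changed sign after quantile normalisation, such as fermentation in NaCl against CK (-0.04 to 0.06) and ERF in NaCl+MT against NaCl (0.09 to -0.03). Of 2718 alternative values of named genes 2544 kept their side of the threshold and 174 fell short of it. The fold change of ICL in NaCl against CK, near 0, changed sign in 5 of them. Of 130 combinations of a named gene and a comparison, 126 of them past the threshold in the main fit, 80 kept their side of it under every alternative run for them; the minimum of 5 FPKM covers 118. With a minimum of 5 FPKM, which tests fewer genes, the counts were 3684 (NaCl against CK), 2605 (NaCl+MT against NaCl), 123 (NaCl+MT against CK) and 1979 (changed back). Requiring a log2 fold change of at least 1 gave 2497 and 1800 in the first pair of comparisons. Without both NaCl replicates 1 and 3, which leaves 1 NaCl library assumed to vary like the other groups, the counts were 2597, 1754, 1068 and 1319. Leaving out 1 library gave 3908 to 6142, 2325 to 4336, 6 to 875 and 1858 to 3401 genes, the lowest of the last 3 without NaCl+MT replicate 2 (2325 and 1858) and without NaCl+MT replicate 3 (6). The NaCl+MT against CK count was the least stable: 54 without a filter, 133 after median-ratio scaling, 72 with a replicate block, 1082 in a fit of the 6 libraries compared and 3663 with array weights. In the fit of 9 libraries the spread is pooled with NaCl, whose replicates differ most; the cause of the other moves was not tested. The replicate numbers do not pair the samples: deviations of equal number were the closest in 5 of 18 cases, and a block gave 4934, 3498 and 2650 genes for the other counts. With an estimated correlation camera called 0 lists in each comparison, with 3, 0 and 3 of 25 at an unadjusted p under 0.05, while fry called 15, 13 and 3. Leaving out 1 library gave 8 to 10, 4 to 7 (7 without NaCl replicate 3) and 0 to 8 lists (0 without CK replicate 1, 8 without CK replicate 3, 7 without NaCl+MT replicate 2). Depth limits genes of low FPKM most in NaCl replicate 3, with a relative depth of 0.537; absolute depth is unknown.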

Other observations

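Chosen after the result was seen were the gene families described here, the test of shared libraries by covariance, the tests of depth, of RNA from another group and of a stronger response for NaCl replicate 1, and the test of tissue share. Gene families outside the fixed lists were formed from symbol stems, which gave 83 families of at least 5 tested members. Those described were picked from these and do not stand alone. The families of the stems RR (7 members, median -0.75), ROP (6, -0.49) and BHLH (36, -0.29) were also lower by median in NaCl against CK. Other divisions of the libraries were not tried for families. Kinesins, the motor proteins of microtubules and the spindle, were lower with NaCl in 6 of 12 members (median -0.81, camera adjusted p = 7.05e-05, adjusted p = 0.732 with an estimated correlation). With NaCl+MT against NaCl 8 of the 12 rose (median 1.02, camera adjusted p = 2.88e-05, adjusted p = 0.674 with an estimated correlation), or 6 without NaCl+MT replicate 2 or 3. KIN13 (GRMZM2G034828) had an FPKM of 7.81 ± 2.57 in CK, 0.287 ± 0.194 in NaCl and 5.46 ± 0.964 in NaCl+MT (SD, n = 3; limma adjusted p = 1.85e-05 and 0.000102). Of 6 tubulin genes 4 fell with NaCl (median -1.16, camera adjusted p = 0.00657, adjusted p = 0.732 with an estimated correlation) and 4 rose with NaCl+MT against NaCl (median 0.89, camera adjusted p = 0.0455, adjusted p = 0.674 with an estimated correlation, and 0.0777 without NaCl replicate 3; 2 rose without NaCl+MT replicate 2). TUB8 (GRMZM2G472945) went from 3.14 ± 0.751 in CK to 0.168 ± 0.137 in NaCl and 2.08 ± 0.251 in NaCl+MT. Of 5 YABBY genes, transcription factors of leaf polarity, 4 fell with NaCl (median -1.37, camera adjusted p = 0.00657, adjusted p = 0.732 with an estimated correlation) and 4 rose with NaCl+MT against NaCl (median 1.20, camera adjusted p = 0.00735, adjusted p = 0.674 with an estimated correlation), with YAB6 (GRMZM2G074124) at 2.23 ± 0.948, 0.228 ± 0.153 and 2.72 ± 0.543 in CK, NaCl and NaCl+MT. None of the 83 families was called with an estimated correlation.

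Benzoxazinoid genes make defence compounds of young maize. Their FPKM in CK ran from 17.1 ± 2.31 for BX14 to 4489 ± 1577 for bx1. Of 9 members 6 fell and 1 rose (median -2.32), while the family as a whole was not called (camera adjusted p = 0.0724, adjusted p = 0.821 with an estimated correlation). The 3 NaCl libraries differed widely: bx1 had an FPKM of 0.211, 195 and 339 in NaCl replicates 1, 2 and 3, BX3 (GRMZM2G167549) 51.7, 425 and 425, and BX5 (GRMZM2G063756) 77.3, 919 and 871. BX14 (GRMZM2G127418) went the other way, at 281, 46.2 and 34.6. The number that fell was 2 without CK replicate 1, 2 or 3, where the rise of BX14 was also lost, and 3 without NaCl+MT replicate 1, 2 or 3. At the preset correlation the family was called without CK replicate 1 (camera adjusted p = 0.0391), NaCl replicate 1 (0.00311) or NaCl replicate 2 (0.0243).

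The 3073 genes changed by NaCl and changed back by NaCl+MT were set against technical explanations. Of 100 assignments of the 9 libraries to 3 groups, the real one included, 1 gave as many. The 2 others that kept the 3 NaCl libraries together gave 2409 and 2468, and all that divided them gave 0. The count thus shows that the NaCl libraries stand apart from the rest. It cannot separate melatonin from another difference of the NaCl seeds. In simulated unchanged groups with the same spread in every group, the covariance of the fold changes was 13.4 times smaller than the one seen. The NaCl replicates differed most, so this ratio is too large by an amount that was not computed. Without NaCl replicate 1, 100% of the 3073 genes, which were chosen with that library included, kept both signs. This was nearly fixed in advance and decides nothing. Groups did not overlap in 5702 of the 5808 genes called in NaCl against CK and 4129 of the 4164 in NaCl+MT against NaCl. In such genes leaving out 1 library cannot turn a sign. Without NaCl replicate 1, 2778 genes were called. Without the shallow NaCl replicate 3, 2681 were called. After median-ratio scaling 3072 genes were called, so scaling is not the whole cause. A response of the seeds to salt that is smaller when melatonin is given remains a hypothesis, which may hold together with a batch or harvest difference of the NaCl seeds that the labels do not give.

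NaCl replicate 1 lay further from CK than NaCl replicates 2 and 3, by 31.5 on the first component beyond the higher of these. That position is on the far side from CK and NaCl+MT, so RNA of another group in NaCl replicate 1 does not account for it. The test does not cover RNA of another group in NaCl replicates 2 and 3, which could leave the same gap. Its relative depth of 1.16 was inside the range of the other libraries, and 98.0% of the gap was left after removal of the 46 genes that were among the 20 highest of any library. A stronger form of the salt response may account for it. Across 22379 genes, which are not independent replicates, the difference of replicate 1 from replicate 2 correlated with that of replicate 3 from CK at Pearson r = 0.232, and with replicates 2 and 3 exchanged at 0.165, between the bounds of 0.1 and 0.3 set after the data were seen, so the explanation stays open.

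The fall of cell cycle and histone genes with NaCl may come from a lower share of growing embryo tissue in the RNA. Endosperm genes should then rise. The median of the starch synthesis list was -0.31 (95% interval -0.44 to 0.13 over 10000 resamples of genes), and -0.32 (-0.46 to 0.09) without Agpat4, agp and ss2, which fit other families. The storage list, with a median of 0.49 (0.26 to 0.84), was not called (camera adjusted p = 0.193, 0.612 with an estimated correlation), and it mixes embryo and endosperm genes with GLB1 and zpu1 of other families, so it decides nothing. The rule on the interval was added after the median was seen, and the interval of the starch list includes 0, so a change of tissue share and a change within cells cannot be told apart; a direct effect of salt stays open and was not tested.

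The 6 libraries of each comparison can be divided into equal groups in only 10 ways, which is too few for a share under 0.05. The real counts of changed genes were 5808, 4164 and 215, each reached by 1 of the 10 divisions, and the highest other count was 0 by limma in each comparison, with up to 1711, 1264 and 782 genes at an unadjusted p under 0.05. For gene lists, 2, 4 and 6 of the 10 divisions called as many as the real 10, 4 and 4, and the highest others called 10, 7 and 8. The list counts therefore did not stand above those of other divisions.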
